A study of Homo sapiens with 6 samples.

How the data were processed

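The series set out to map where FoxN3, a forkhead transcription factor, binds in the genome of HepG2 cells. These are an established human hepatocellular carcinoma line widely used as a liver model. Chromatin immunoprecipitation followed by sequencing (ChIP-seq) isolates formaldehyde-fixed DNA fragments with an antibody and counts where they map. Per the labels, 4 ChIP libraries came from replicates A and B with 2 sequencing runs each, and 2 libraries were runs of 1 control made without antibody.

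Per the submitters' processing notes, the authors used CASAVA 1.8, Bowtie 1.1.1 and MACS2 2.1.1.20160309 with the hg38 genome build. The thresholds, the duplicate handling and the read filters are not given in the sources used here. The file analysed is 1 peak list in the MACS2 narrowPeak layout, called on merged ChIP replicates against the control. The labels name replicates A and B, whereas the peak names carry the letters B and D, and this was left open. For each peak the authors deposited the interval, the summit (the base with the highest enrichment), the fold enrichment of the pooled ChIP signal over the local control background, and the −log10 p and −log10 q values at the summit. The display score the authors deposited is 10 times the −log10 q value cut to a whole number and was not used further. Fold and q are the authors' values throughout and served only to describe, rank and filter peaks within this list. Because the list pools the replicates, no value has a replicate error, and p-values describe this list of peaks or genes, not replicate cultures.

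The main set held the deposited peaks with a −log10 q of 2 or more on chromosomes 1 to 22, X and Y. MACS2 computes fold as (k + 1)/(λ + 1) and p from a Poisson distribution, where k is the number of ChIP fragments over the summit and λ the local control background scaled to the ChIP depth. Solving both expressions for a whole k recovered k and λ for 100% of main-set summits within 0.001 on the −log10 p scale. On 3000 simulated peaks this recovered 100% of the fragment numbers. The smallest background in the main set was 2.25 fragments per position, a floor shared by 4.47% of summits. The median main-set summit had 17 ChIP fragments, with an exact 95% Poisson interval of 9.90 to 27.2. Intervals cover counting error only, since the list is pooled. The fragments carried no molecular identifiers, so undetected duplicates would make the intervals of fragment numbers too narrow.

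Genes came from the RefSeq annotation of GRCh38.p14, which shares its chromosome coordinates with hg38. The table used here gave gene starts and ends without strand or exons. A promoter was therefore replaced by a gene boundary: a summit within 1 kb of either end of a protein-coding gene. Summits were classed as boundary, body of a protein-coding gene, other gene, or outside genes, and exons, introns and untranslated regions were not separated. Each class was compared with 10 random positions per summit on the same chromosome by a two-sided Fisher's exact test, with Benjamini-Hochberg adjustment over the 4 classes. Random positions were drawn between the outermost genes or peaks of a chromosome, so assembly gaps were included. Coordinates below are 1-based on hg38.

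For 28 gene lists fixed before the data were examined, the share of genes with a main-set summit at a boundary was compared with all other protein-coding genes by a two-sided Fisher's exact test, adjusted over the lists. A summit can count for neighbouring genes. The planned random lists matched on promoter GC and CpG content needed sequence, and 10000 random lists matched on gene length and on summit density 5 to 100 kb away, each in 5 quantiles, replaced them. In simulated lists of 40 genes, the test before adjustment called 83% of lists in which 50% of genes had a summit. It called 72% of those at 90% and 3% of those at the genome-wide share. The simulated genes were independent and no adjustment was made, so the 83% and 72% overstate the power of the adjusted test, more so in shorter lists. Shares have 95% Wilson intervals. Relations across the 24 chromosomes were tested with 100000 permutations. Motif, k-mer and motif-position analyses were planned, needed the genome sequence, and were not analysed here.

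Named peaks followed a rule set beforehand. It took the 15 boundary and 10 distal main-set summits with the largest −log10 q, 1 per nearest gene, the 2 members of each list with the largest value, and a fixed set of single genes. Its parts on soft-masked sequence and motifs were not applied, and 2 list symbols had no match among protein-coding genes. Some genes that the rule names are not reported here. Alternatives varied the q threshold, the fold, the number of peaks, the merging distance, the window around a boundary and the genes that define boundaries. Those added after seeing the data shifted summits by 20 kb, left out 10 Mb bins with a median control background of 4.5 or more, and changed the definition of the strongest summits. Computations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.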

Results

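The deposited list placed FoxN3 ChIP signal in HepG2 cells at 202636 positions, from 4 libraries of replicates A and B merged and compared with 2 runs of a control without antibody. The series addresses how forkhead factors can recognise more than 1 kind of DNA site. The peak list shows where in the genome the antibody gave signal above a control without antibody. Whether FoxN3 itself was bound at each position was not tested. The main set held 198749 summits, 98.1% of the list. Their peaks had a median width of 307 bp and covered 79.8 Mb. Enrichment was modest at most positions. The median fold over background was 3.76, 39.4% of summits reached a fold of 4 and 0.642% a fold of 10. The median summit rested on 17 ChIP fragments over a control background of 3.71. Summits lay close together, with a median of 984 bp to the nearest neighbouring summit. There are no per-replicate values, so no value below has a replicate error.

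FoxN3 summits gathered at the ends of protein-coding genes. Of the main-set summits, 13.3% (95% interval 13.2 to 13.5%) lay within 1 kb of a gene boundary against 2.98% of random positions, an odds ratio of 5.01 (4.94 to 5.09). The bodies of protein-coding genes held 52.3% of summits and 41.9% of random positions, an odds ratio of 1.52 (1.504 to 1.533). Regions outside annotated genes held 25.7% against 42.2%, an odds ratio of 0.47 (0.47 to 0.48). All 4 classes passed Fisher's exact test after adjustment, with a −log10 adjusted p of 7488 for boundaries. The test counts summits as independent, although many are close neighbours: merging peaks within 500 bp left 138752 regions. The p-values and intervals of summit shares are therefore too narrow. Against positions 20 kb to either side of the same summits, the boundary odds ratio was 2.52 (2.48 to 2.57) and the gene-body odds ratio turned to 0.97 (0.96 to 0.98). Among the 5000 peaks with the smallest p, the boundary share was 27.5% and the gene-body odds ratio was 0.72 (0.68 to 0.77).

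**Figure D1:**
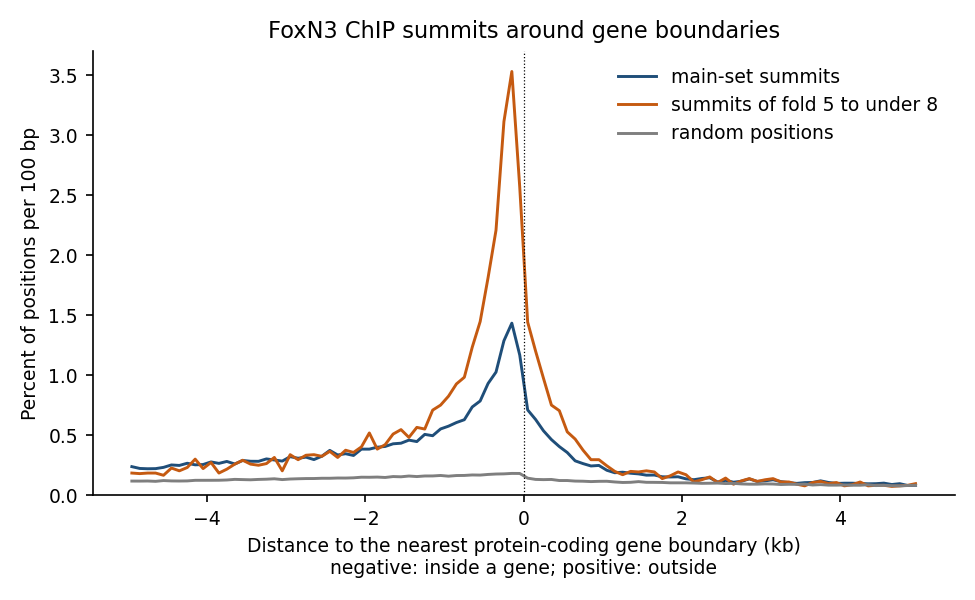
Percent of positions per 100 bp by distance to the nearest protein-coding gene boundary, in kb, with negative distances inside a gene. Lines show main-set summits, summits of fold 5 to under 8, and random positions; the main set reached 1.43% and the fold 5 to 8 summits 3.53% in the bin starting 200 bp inside the boundary, where random positions had 0.183%.

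The strongest boundary summits included FOXJ1 and genes of motile cilia. Two-part cilia lists were written after the 45 strongest summits were seen, and the genes of those summits were left out. In both parts together 15 of 187 genes had a boundary summit of fold 10 or more (Fisher's exact p = 1.6e-15). The comparison was with 65 of 19803 genes outside cilia lists. Of the motile cilia genes 14 of 125 had one (Fisher's exact p = 1.2e-16). Of the ciliary transport and basal body genes it was 1 of 62 (Fisher's exact p = 0.37). The 14 include CCDC39, PIERCE1 and DNAAF19, which are named below. The lists do not hold every cilia gene: ALMS1, FAM161A and CEP126, also named below, count among the 65. The 1 of 62 therefore describes that list and not all basal body genes. The largest boundary summit by −log10 q, at 187, was at FOXJ1, the forkhead factor that directs the formation of motile cilia. Its peak spanned 76140094 to 76142366 on chromosome 17, with the summit 75 bp from the gene boundary, 192 ChIP fragments and a fold of 23.03. A summit 25 bp from LRGUK, a gene needed for sperm tail assembly, lay in a peak at 134127050 to 134127819 on chromosome 7 and had a fold of 23.9. At CFAP43, which encodes an axonemal protein of cilia and flagella, the peak spanned 104231813 to 104232518 on chromosome 10 and the fold was 27.1, with 87 fragments. Other cilia genes among the 15 strongest were CCDC39, an axonemal ruler protein, with a fold of 18.5, PIERCE1, a protein of the ciliary microtubules, with 15.99, and DNAAF19, an assembly factor of axonemal dyneins, with 13.6. ALMS1, a basal body protein, had a fold of 16.6, the centrosomal gene CEP126 17.2, the photoreceptor cilium gene FAM161A 13.2 and the NIMA-family kinase NEK10 17.99. The rest were ZNF497, a zinc finger gene, with a fold of 25.2, the apoptosis inhibitor API5 with 23.4, GTF2E2, which encodes a subunit of the general factor TFIIE, with 18.03, STK11IP with 15.4 and DZANK1 with 13.6. The DZANK1 summit also lay within 1 kb of POLR3F, a subunit of RNA polymerase III, the PIERCE1 summit of the mitochondrial ribosomal gene MRPS2, and the DNAAF19 summit of the splicing factor gene EFTUD2.

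The largest enrichment of the list was distal. It lay inside TNRC6A, a component of microRNA-guided silencing, in a peak at 24663934 to 24664928 on chromosome 16, 54.3 kb from the nearest gene boundary, with 168 fragments, a fold of 41.04 and a −log10 q of 213. Summits inside ACSM2B, an acyl-CoA synthetase gene, and inside APLF, a DNA repair factor gene, had folds of 36.6 and 34.4. Other summits lay outside protein-coding genes, nearest to NYAP2, the integrin gene ITGA4, the methylmalonyl-CoA mutase gene MMUT and the ephrin receptor gene EPHA4. They were 284, 168, 333 and 152 kb from the boundary, with folds of 36.3, 36.0, 35.0 and 34.7. The other distal summits of the 10 strongest lay inside CDYL, a chromodomain gene, with a fold of 34.7, inside TSPAN12, a tetraspanin gene, with 32.8, and inside MACROD2, 617 kb from the nearest boundary at FLRT3, with 24.6. Of these 10 distal summits, those at ACSM2B, NYAP2, ITGA4, MMUT, EPHA4 and CDYL had a control background at the floor of 2.25.

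Location changed with enrichment. The boundary share rose from 10.0% (9.65 to 10.4%) of summits under fold 3 to 32.4% (31.2 to 33.7%) at fold 6 to 8, and was 6.39% (4.92 to 8.27%) at fold 10 to 15 and 3.55% (1.52 to 8.03%) at fold 20 or more. Of the 1275 summits of fold 10 or more, 70 lay at a boundary (5.49%, 4.37 to 6.88%) against 13.4% of the others (Fisher's exact p = 5.2e-20). Over 50 kb from every boundary lay 52.9% (50.2 to 55.7%) of the 1275 and 23.6% of the others. Random positions were not counted at this distance. Against random positions the boundary share of the 1275 was still raised, with an odds ratio of 2.35 (1.804 to 3.07) and 2.41% of random positions at a boundary. Their other odds ratios against random positions were 0.82 (0.73 to 0.93) in gene bodies, 0.93 (0.78 to 1.11) in other genes and 1.097 (0.98 to 1.23) outside genes. The gene-body direction was opposite to that of the main set, but the 2 sets were not tested against each other by these classes. Against positions 20 kb to either side, the gene-body odds ratio was 0.86 (0.75 to 0.99). It did not pass Fisher's exact test there (−log10 adjusted p of 1.05), and the main set also lay under 1, at 0.97. Their peaks had a median width of 522 bp and a median of 46 fragments, and the nearest other summit was a median of 9.07 kb away. Ranking by ChIP fragments turned the comparison: of the 1275 summits with the most fragments, 23.5% (21.2 to 25.9%) lay at a boundary.

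**Figure D2:**
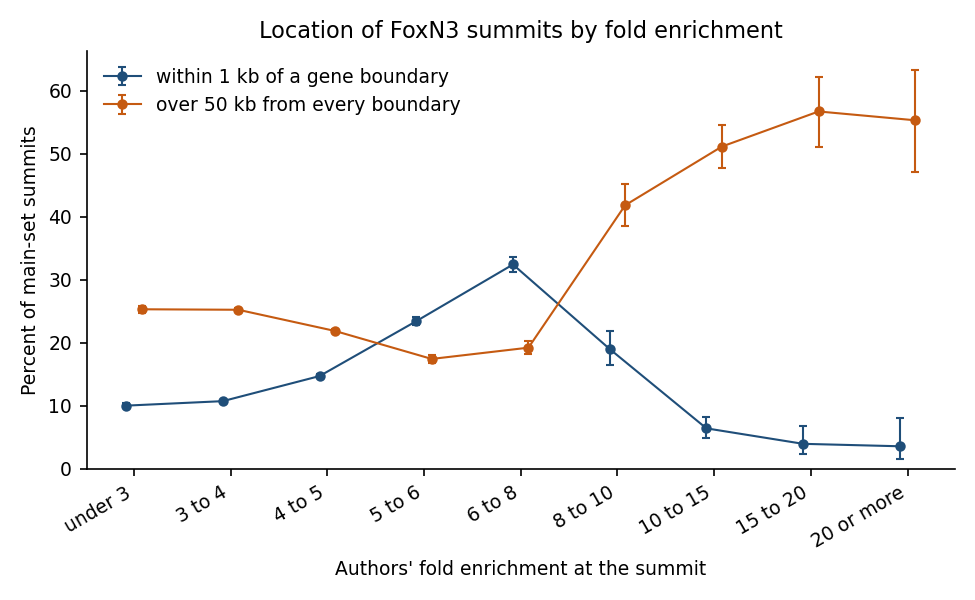
Percent of main-set summits within 1 kb of a protein-coding gene boundary and over 50 kb from every boundary, by the authors' fold enrichment; points are shares and bars are 95% Wilson intervals. The boundary share was highest at fold 6 to 8 (32.4%) and the share over 50 kb away was above 50% from fold 10 upward. The share of random positions over 50 kb away was not computed.

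Most protein-coding genes carried a summit. Of 20037 genes, 14580 (72.8%) had a main-set summit within 1 kb of a boundary, 5139 at both ends. Of the 28 lists, 6 had a higher and 4 a lower share than other genes. The higher lists were Wnt pathway genes (29 of 30, adjusted p = 0.0085 by Fisher's exact test), HOX genes of body patterning (37 of 39, 0.0068), mitosis genes (28 of 30, 0.033), DNA replication genes (40 of 44, 0.020), forkhead genes (36 of 40, 0.041) and cytosolic ribosomal proteins (68 of 78, 0.014). Examples are the Wnt receptor gene FZD5 with a fold of 7.40, the Wnt signal transducer DVL1 with 8.34, the clamp loader subunit RFC5 with 8.83, the primase subunit PRIM2 with 9.11, the cytokinesis motor KIF23 with 13.8, its partner PRC1 with 8.14 and the ribosomal protein gene RPL23 with 8.04. Against random lists of like gene length and local summit density, Wnt, mitosis, forkhead and ribosomal protein genes lay at percentiles 99.9, 99.2, 99.3 and 100, while DNA replication and HOX genes lay at 95.4 and 73.4, inside the middle 95%. The percentiles were not adjusted over the 28 lists. Lists without a call also lay outside the middle 95%: oxidative phosphorylation at 99.4, bile acid genes at 1.53 and blood cell genes at 2.08.

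Plasma protein and xenobiotic metabolism genes had a summit at a boundary less often than other protein-coding genes, of which 72.8% had one. Of random intervals with the lengths of protein-coding genes 18.6% had one, and neither list's share lay below this. Of the plasma and acute-phase proteins 12 of 31 genes had one (38.7%, 23.7 to 56.2%, Fisher's exact adjusted p = 0.0014), the strongest at the retinol carrier RBP4 with a fold of 5.70 and the inhibitor heavy chain ITIH3 with 4.90. Of the xenobiotic metabolism genes 6 of 21 had one (28.6%, 13.8 to 50.0%, Fisher's exact adjusted p = 8.7e-04), led by the cytochrome P450 reductase POR with 6.10 and the dioxin receptor AHR with 4.45. The lists lay at percentiles 0.01 and 0 of matched lists. Olfactory receptors, silent in liver, had summits at 19 of 390 genes (4.87%, 3.14 to 7.48%, Fisher's exact adjusted p = 3.7e-183). Replication-dependent histones had them at 30 of 57 (Fisher's exact adjusted p = 0.0085), at percentile 17.5 of matched lists.

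The other 18 lists did not pass the threshold, with shares from 50.0 to 90.9%. Among liver programmes, 20 of 24 cholesterol synthesis genes had a summit, including MVD, which encodes an enzyme of the mevalonate pathway, with a fold of 6.80. Fatty acid and triglyceride synthesis had 19 of 21, including FASN (5.60) and ACLY (5.40), fatty acid oxidation 20 of 22, including ETFDH (6.67), and gluconeogenesis and glucose handling 20 of 25, including PCK2 (5.71). Liver transcription factors had 20 of 23, apolipoproteins 14 of 18, including APOB (7.39), coagulation 10 of 18 and bile acid genes 9 of 18. Of the 10 calls, 7 held at a −log10 q of 5, 5 at a fold of 4, and only the low share of olfactory receptors among the 5000 peaks with the smallest p. Plasma protein and xenobiotic lists kept their lower share under every other threshold and window run, whereas each of the 6 higher calls ended under at least 2 alternatives besides the 5000 peaks. The Wnt call ended within 500 bp (odds ratio 1.27, Fisher's exact adjusted p = 0.78) and without 10 Mb bins of raised control background (8.17, 0.058), and the forkhead call (3.37) at a −log10 q of 5 (1.07) and a fold of 4 (1.37). Without those bins the forkhead odds ratio stayed close to its value, at 3.13, and Fisher's exact adjusted p was 0.17.

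**Figure D3:**
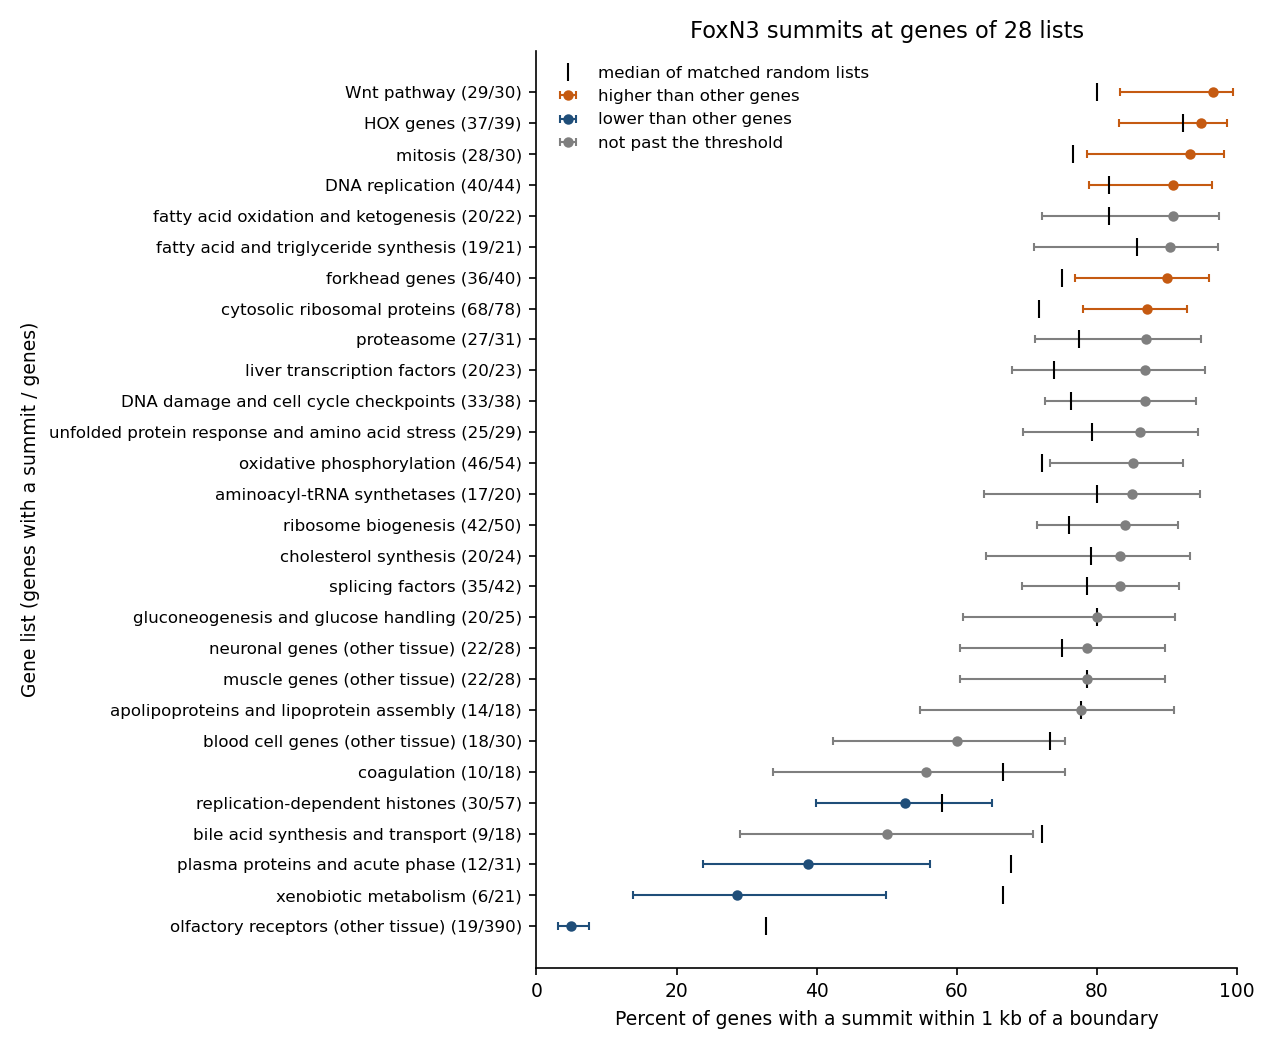
Percent of genes with a main-set summit within 1 kb of a boundary in each of 28 lists; points are shares, bars 95% Wilson intervals and vertical ticks the median of 10000 matched random lists. Wnt pathway genes (29 of 30) and olfactory receptors (19 of 390) mark the ends, and the colours mark lists past the adjusted threshold.

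Among single genes, the FOXN3 gene itself had a summit 164 bp from a boundary with a fold of 3.74 and 15 fragments. The pioneer factor genes FOXA1 and FOXA2 had folds of 5.59 and 5.79, FOXA3 4.24 and the paralogue FOXN4 3.53. The proto-oncogene MYC had a fold of 3.69, the cell cycle inhibitor CDKN1A 4.39, the gluconeogenic gene PCK1 3.69, the lipoprotein gene APOA1 4.90 and the hepatocyte factor HNF4A 2.71. The corepressor SIN3A had 6.62, SKIC8 6.10 and MEN1 5.33. At a −log10 q of 5 no summit was left at FOXN3, FOXN4 and FOXA3. At a fold of 4 none was left at FOXN3, FOXN4, MYC, PCK1 and HNF4A. The summits at MYC, PCK1 and HNF4A had 33, 31 and 35 fragments over control backgrounds of 8.20, 7.67 and 12.3. Those at FOXN3 and FOXN4 had 15 and 17 fragments over 3.28 and 4.10. The albumin gene ALB, FOXN2, G6PC1 and PIM2 had no main-set summit within 1 kb of a boundary, but 3 of them had one within 5 kb.

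Summit density differed between chromosomes. Chromosome 19 held 216 summits per Mb, 20 169, 17 161, 22 157 and 16 134, against 27.7 on chromosome 13, 6.36 on X and 1.05 on Y. Of the protein-coding genes on X, 27.4% (24.5 to 30.5%) had a summit at a boundary, on Y 4 of 63, and on chromosome 20 91.1% (88.3 to 93.2%). The median control background at summits was 6.56 fragments on chromosome 20, 5.39 on 2, 4.92 on 16, 4.75 on 6 and 4.73 on 17, 3.28 on most other autosomes, and at the floor of 2.25 on X and Y. On chromosome 14 it was 9.02 between 20 and 30 Mb, against 3.43 for the whole chromosome. Across 24 chromosomes, summits per Mb rose with protein-coding genes per Mb (Pearson's r = 0.84, Spearman's rho = 0.84, each with a permutation p of 1e-05, the smallest the draws can give, and 4e-05 adjusted over 4 relations). Without chromosomes 17 and 19 r was 0.77. They also rose with the control background (r = 0.54, permutation p = 0.0079, adjusted 0.011; rho = 0.74, permutation p = 1e-04, adjusted 2e-04; r = 0.49 without chromosomes 2 and 20). Summits of fold 10 or more per Mb followed genes per Mb by Pearson's r of 0.59 (permutation p = 0.0076, adjusted 0.011) and not by rank (rho = 0.12, permutation p = 0.58), and r was 0.30 without chromosomes 17 and 19, which were left out together. With the control background they gave r = 0.44 (permutation p = 0.037) and rho = 0.22 (permutation p = 0.31).

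**Figure D4:**
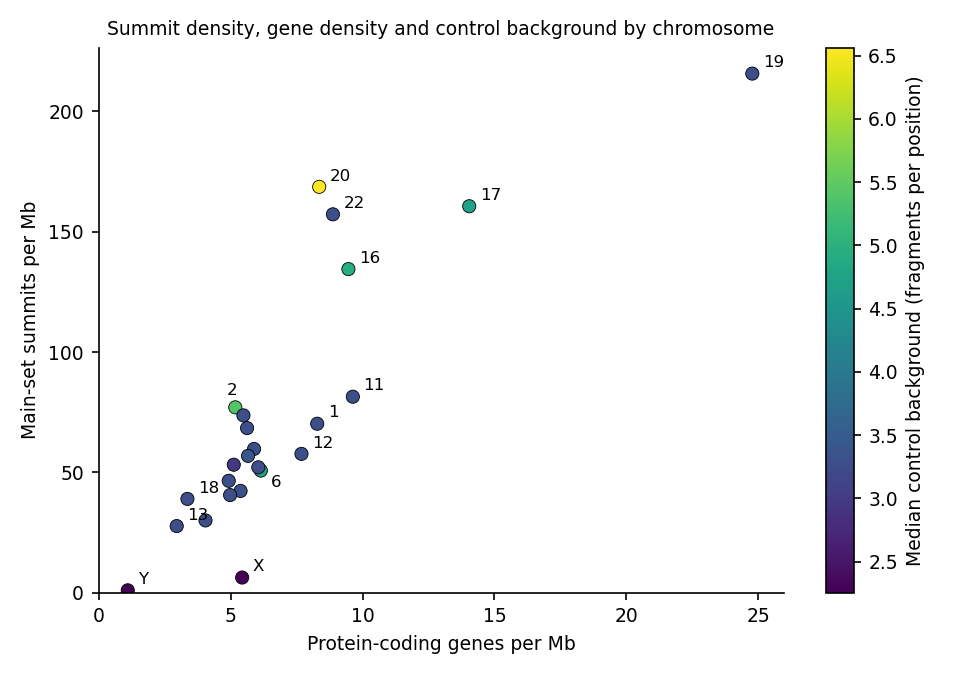
Main-set summits per Mb against protein-coding genes per Mb, 1 point per chromosome, coloured by the median control background at summits in fragments per position. Chromosome 19 lies highest at 216 summits per Mb, and X, at the background floor, has 6.36.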

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

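Tests on peak width, on the control background at strong summits and within strata of background were chosen only after the location of the strongest summits was seen. So was the test without bins of raised background. The strata were first compared with summits of fold 6 to 8, the class with the largest boundary share, and then with all other summits, which is the comparison given below. The peaks outside the assembled chromosomes entered no comparison. The list held 147 peaks on 37 unplaced, unlocalised or alternate contigs, called above the control, of which 40 lay on 1 unlocalised contig of chromosome 14 with a median background of 10.4 fragments. It also held 3 peaks on the mitochondrial chromosome, with a median fold of 1.403 over a background of 265 fragments.

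The summits of fold 10 or more lay at gene boundaries less often than other summits, at 5.49% against 13.4%, though more often than random positions at 2.41%. A low background in the ratio may account for part of this, since the same number of summits ranked by ChIP fragments had 23.5% at a boundary, but it is not the whole cause at the floor background, where 8 of 733 against 9.39% of other summits lay at a boundary (odds ratio 0.11, 0.053 to 0.21). Above the floor the explanation stays open, because the shares of 11.4% and 13.6% gave an odds ratio within strata of background of 0.85 (0.65 to 1.11, Mantel-Haenszel) that includes 1, and single strata went both ways, from 0.60 (0.32 to 1.16) to 3.98 (1.45 to 10.9). Stacked duplicate fragments alone would leave peaks close to 1 fragment wide, whereas the median width was 522 bp. Duplicates within wider peaks stay open, because width cannot show them and the duplicate handling is not given. Gained DNA in 10 Mb bins is not the whole cause, since the odds ratio was 0.32 (0.24 to 0.43) without bins of raised background and 0.38 (0.30 to 0.48) with them. Collapsed repeats and shorter gains stay open, since a high fold itself selects a low background and the median of 2.25 fragments decides nothing, and no biological explanation was tested, since neither sequence nor a second factor was used here.

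Summit density differed between parts of the genome. Gene density is a candidate explanation, with a rho of 0.84 across chromosomes, and deeper coverage of gained DNA is another. Bins of 10 Mb with a raised control background held 1.68 times as many summits per protein-coding gene as other bins (bootstrap interval over bins 1.37 to 2.07), and 1.16 times as many of fold 4 or more (0.95 to 1.43). The bootstrap treats bins as independent, whereas raised bins form runs on a few chromosomes, so both intervals may be too narrow. The explanations are not exclusive, and a fold cut also favours regions of low background, where few fragments reach it. Copy number was not measured here, and no biological explanation was tested.

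Genes of plasma proteins and xenobiotic metabolism had a summit at a boundary less often than other protein-coding genes. Gene length and neighbourhood do not account for it, since both lists lay at or under percentile 0.01 of lists matched on length and local summit density. Promoter CpG content stays open, because it needs sequence, as does the low activity of some of these genes in a cultured line. No biological explanation was tested.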

How the results depend on the processing

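Shifted summits, bins of raised background and other definitions of the strongest summits were alternatives chosen after the data were seen. The number of summits, 198749, was 87763 at a −log10 q of 5, 78282 at a fold of 4 and 5000 by construction among the smallest p. The boundary, other-gene and outside-gene odds ratios kept their direction and their side of the threshold under every alternative run, with 2.52 to 13.6 for boundaries, except that the other-gene class was empty, and not tested, with boundaries of all genes. The summits of fold 10 or more, described above, are not among these alternatives and did not have the lower odds ratio outside genes. The gene-body odds ratio of 1.52 reversed to 0.72 among the 5000 peaks and to 0.97 against shifted summits, and the cause was not tested. The share of genes with a summit, 72.8%, was 58.4% at a −log10 q of 5, 7.88% with 5000 peaks, 54.9% at a fold of 4, 64.8% within 500 bp, 79.7% within 5 kb and 71.0% without bins of raised background. Higher lists fell from 6 to 3 at a −log10 q of 5, 2 at a fold of 4, 1 of them new, 2 without those bins, 4 within 5 kb and 0 with 5000 peaks, where 1 list was lower. Within 500 bp 6 lists were higher, 3 of them among the original 6, and Wnt, mitosis and DNA replication genes were lost. Fatty acid and triglyceride synthesis was newly higher at a fold of 4 (odds ratio 4.94, Fisher's exact adjusted p = 0.030) and within 500 bp (5.17, 0.042). Coagulation genes were newly lower within 500 bp (0.21, Fisher's exact adjusted p = 0.015). The lower histone call ended within 5 kb (0.65, Fisher's exact adjusted p = 0.31). With 5000 peaks the odds ratios of ribosomal proteins and HOX genes reversed to 0.63 and 0.15, neither past the threshold, and few genes have a summit there. The boundary share of the strongest summits, 5.49%, reversed against other summits to 23.5% when ranked by fragments and kept its direction in the other 4 definitions, at 3.81 to 11.2%. Of 196 values for single lists under alternatives, 164 were on the same side of the threshold, 25 kept their direction and were no longer past it, 2 reversed and were no longer past it, and 5 were newly past it.

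The alternatives for motif enrichment, k-mers, motif position, co-occurrence, promoter state and peak strength were not run, because the genome sequence was not used here. Leaving out a replicate was not possible on a pooled list. No paired analysis was possible because the list holds no value of a single replicate. No main-set summit had fewer than 9 fragments, a number reached at the floor background, so weaker sites were not detectable at this depth on any chromosome. Whether this limit contributes to the low summit density on X was not tested.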

Other observations

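The cilia gene lists were written after the 45 strongest summits had been seen, and the genes of those summits were left out of the test.

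Genes that do not code for protein also carried summits. A main-set summit lay within 1 kb of a boundary of 193 of 443 tRNA genes (43.6%, 39.0 to 48.2%) against 10.9% of random intervals of the same lengths, an odds ratio of 6.31 (5.11 to 7.78). Long noncoding RNA genes had 38.2% against 16.2% (odds ratio 3.19, 3.09 to 3.30) and microRNA genes 37.3% against 12.01% (4.35, 3.93 to 4.82). Small nucleolar RNA genes had 16.3% against 10.9%, and small nuclear RNA genes 14.9% against 14.8% (odds ratio 1.01, 0.63 to 1.61). Pseudogenes lay below random intervals, with 10.9% against 12.04% (odds ratio 0.89, 0.85 to 0.94), and those annotated as transcribed above them, with 25.8% against 17.4% (1.64, 1.44 to 1.88). None of 49 annotated ribosomal RNA genes had a summit, with a 95% Wilson upper limit of 7.27%. Overlap with the boundaries of protein-coding genes was not removed.

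A summit of fold 10 or more lay at a boundary of 84 protein-coding genes. Cilia genes outside the cilia lists, such as ALMS1 and FAM161A, are among the 84. Of the 84, 17 belong to lists of motile cilia and of ciliary transport genes. Beside those already named they include the dynein heavy chain DNAH7 with a fold of 11.1, the radial spoke gene RSPH1 with 12.95, the flagellar gene SPEF2 with 10.5, the dynein assembly factor DNAAF5 with 17.4, the light chain DNAL1 with 11.3, the adenylate kinase AK8 with 14.2, CFAP53 with 13.4, CFAP69 with 11.4, CFAP99 with 12.1, CFAP263 with 11.1, CFAP298 with 10.4 and the transition zone gene TCTN1 with 10.7. Of the 28 lists fixed beforehand, members at this fold were FOXJ1, KIF23, the tryptophanyl-tRNA synthetase WARS1 and the muscle actinin ACTN2, and no list passed Fisher's exact test for such summits, with an unadjusted p of 0.16 or more and an adjusted p of 1 in each.

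The hypothesis tested was that cilia genes hold strong summits more often than other genes. Without the genes of the 45 strongest summits, 15 of 187 cilia genes (8.02%, 4.92 to 12.8%) had a summit of fold 10 or more at a boundary against 65 of 19803 other genes (0.328%, 0.258 to 0.418%), a ratio of 24.4 (Fisher's exact p = 1.6e-15). Among genes with any main-set summit the ratio was 20.0. In the motile cilia and axoneme list 14 of 125 genes had such a summit, among them CCDC39, PIERCE1 and DNAAF19 from the 15 strongest boundary summits. In the ciliary transport and basal body list, 1 of 62 had such a summit (Fisher's exact p = 0.37), and 6 of 62 had one of fold 8 or more (Fisher's exact p = 2.4e-04). The lists were not tested against each other. They do not hold every cilia gene, since the basal body gene ALMS1 and the photoreceptor cilium gene FAM161A count among the 65 other genes. Any main-set summit was present at 88.8% of cilia genes and 72.6% of other genes. Strong boundary summits may thus be more frequent at cilia genes in these cells, although only 70 of the 1275 summits of fold 10 or more lay at a boundary, and whether FoxN3, a related forkhead protein recognised by the antibody, or another factor of those promoters brings the signal was not tested.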
